A study of Mus musculus with 11 samples.

How the data were processed

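The series measured RNA by sequencing in female mice of the strain given as C57BL. The labels put 11 samples in 4 groups: 3 control (WT) and 3 Msl2 knockout (Msl2KO) whole brain samples, and 3 control and 2 Msl2KO placenta samples. Groups were taken from the titles, which also carry the number 18 beside the word for female; its meaning is not stated. The source field names neural progenitor cells for all 11 samples, against the tissue in the titles, and the culture and knockout protocols describe embryonic stem cells and neural progenitors rather than mouse tissue. How the Msl2KO mice were made, and which strain the allele came from, is not given in the sources used here. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

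The 2 files used were the authors' own comparison tables, 1 per tissue, each with 47937 genes. Values per sample were not analysed here, so the depth of each library is unknown and the number of samples that show a direction cannot be given. Per the file headers, the tables are DESeq2 results, and per the submitters' processing notes the tools of the series include Trim Galore 0.6.5, STAR 2.7.4 and 2.7.9a, featureCounts 2.0.0 and DESeq2 (version not given), with genome build mm10. Those notes cover several assays and give no order or settings. The annotation, the treatment of reads with several matches and the use of strand in counting are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies, may therefore be divided between genes.

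The deposited mean per gene is a signal value, the authors' mean over the libraries of a tissue of counts divided by size factors. It has no error and spans both genotypes. The authors' fold change and its standard error are on the log2 scale, and the ratio of the first to the second equalled the deposited score, a Wald statistic, to within 5.33e-14 in every gene with values, so the fold changes were not shrunken. The deposited p-value and Benjamini-Hochberg adjusted p-value were taken as they stood, and every gene the authors marked as up or down had an adjusted p under 0.05. The tables do not state the direction of the ratio; it was read as Msl2KO over WT because Msl2 itself was negative in both tissues, so the sign of Msl2 is no independent check of the labels. An adjusted p was present for 16694 genes in whole brain, where the lowest mean normalized count was 22.4, and for 16616 in placenta, where it was 5.78. Genes without one were treated as not tested, and 2 whole brain genes had a fold change but no p-value. The summed mean normalized counts came to 24.2 M in whole brain and 12.2 M in placenta (M, 10 to the power of 6). The median standard error of tested genes was 0.0936 in whole brain and 0.218 in placenta on the log2 scale, so placenta changes had to be larger to be called.

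The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says that a choice came after. A gene was called where the authors' adjusted p was under 0.05. Because no values per sample were used, no count model was refitted; this is the branch of the design for tables that hold only a comparison. Errors after ± are standard errors. Differences between tissues were tested per gene as the difference of the log2 fold changes over the root of their summed squared standard errors (two-sided normal test, Benjamini-Hochberg adjustment over the 14184 genes tested in both). The libraries of the tissues are separate, so no control library is shared. Whether the tissues came from the same animals is not stated. The difference test, and the overlap expected for independent lists, treat the tissues as independent. Overlap of calls was tested per direction with a one-sided Fisher's exact test.

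The gene lists (64, some used in 1 tissue only) cover chromatin complexes, imprinting, cell cycle, stress, signalling and the cell types of each tissue. Lists with at least 5 tested members were tested with limma 3.58.1 (cameraPR, R 4.3.3) on the deposited Wald score, with a preset correlation of 0.01 and adjustment over the lists of a tissue. A correlation between genes could not be estimated without values per sample, so a preset correlation of 0.05 was run in its place, with a rank-based form. Beside each list stand the members called over all genes and those called when p-values were adjusted over the list alone. X-linked and autosomal genes with a mean normalized count of at least 10 were compared by their median log2 fold change, against 10000 random lists matched on expression.

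Genes were placed by identifier, without version, on the GENCODE M21 annotation of build GRCm38, the assembly also called mm10; 47310 of the 47937 identifiers were found there, 39192 of them with the same version. Transcripts of called pseudogenes were matched to protein-coding transcripts with BLAST+ 2.17.0. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

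Genes named in the text follow a rule. It takes the members of the MSL complex, and, among called genes with a mean of at least 50 and a conventional symbol, the 8 highest and 8 lowest fold changes and the 4 smallest adjusted p-values per direction. It adds up to 4 members per described list with the smallest p in the direction of the list, the 8 leading genes called in both tissues, the 8 leading tissue differences, Xist and Y-linked genes. Called members of the lists described in the report are also named. Other genes are said to be chosen after their values were seen.

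The steps were tested on simulated data with the real genes' standard errors and 200 changed genes. In whole brain, 32.4% of genes changed by 0.25 on the log2 scale were called, 72.7% at 0.5 and 82.5% at 1, and 6.11% of calls were at unchanged genes. For placenta these shares were 1.32%, 16.4% and 63.5%, with 10.5% of 57 calls at unchanged genes. So fewer calls in placenta do not mean fewer changed genes. For differences between tissues they were 0.8%, 21.1% and 56.4%, with 6.52% false. Alternatives covered the threshold, the size of the change, the adjustment, the null distribution, centring, filters on the mean and, chosen after seeing the data, leaving out chromosome 9, Msl2 with the locus in its intron, members of the decidual and related lists, or genes with a standard error above 0.5.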

Results

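RNA was sequenced from whole brain and placenta of female mice, with and without Msl2, the ubiquitin ligase subunit of the MSL histone acetyltransferase complex. Whole brain had 3 WT and 3 Msl2KO samples, and placenta had 3 WT and 2 Msl2KO samples. The title of the series presents MSL2 as a sensor of allelic dosage in mammals, and the comparison of genotypes within each tissue asks which genes depend on it. Values are those of the authors' comparison tables, given as log2 fold changes of Msl2KO over WT ± standard error, with the authors' mean normalized count per gene where a level is given. The titles name the tissue, whereas the source field names neural progenitor cells for every sample. The authors' deposited table for placenta gave the prolactin family a median mean normalized count of 827, against 0.486 in that for whole brain. For presynaptic genes the order was opposite, with medians of 6585 in whole brain and 30.4 in placenta in the authors' deposited tables.

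Msl2 was lower in both tissues. On chromosome 9 from 101074101 to 101104800 (build GRCm38, plus strand), Msl2 (ENSMUSG00000066415.4) changed by −1.69 ± 0.06 in whole brain in the authors' deposited table, or to 0.310 of the WT level (adjusted p = 7.5e-161, mean normalized count 1433). The placenta value in the authors' deposited table was −1.88 ± 0.13, or 0.272 of WT (adjusted p = 1.5e-44, mean normalized count 785). Transcripts of Msl2 thus remained in the Msl2KO libraries, and the tables count whole genes, so exons cannot be told apart. No other MSL complex member passed the test. For Msl1 the authors' deposited tables held 0.00 ± 0.04 in whole brain and −0.01 ± 0.11 in placenta, for Msl3 they held 0.09 ± 0.09 and −0.02 ± 0.13, and for Kat8, the H4K16 acetyltransferase, 0.06 ± 0.09 and 0.03 ± 0.20. The female label was checked with the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y, whose mean normalized counts in the authors' deposited tables were at most 1.84 in whole brain and 0.346 in placenta. Xist, the RNA that coats the inactive X, stood at 49887 and 14676 in the authors' deposited tables.

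In whole brain the loss of Msl2 went with many small changes. Of 16694 tested genes, 339 were called, 142 higher and 197 lower, with a median absolute log2 fold change of 0.26 among them, and 25 had an absolute value of at least 1. Among called genes with a mean of at least 50 and a conventional symbol, the largest falls were in Rpl29, a protein of the large ribosomal subunit, at −4.03 ± 0.21 (adjusted p = 2.0e-81) and Ooep, an oocyte-expressed gene, at −3.48 ± 0.33 (adjusted p = 5.1e-22), both in the authors' deposited table. The calcium-binding S100a1 fell to −2.05 ± 0.24, the phosphatase Ppm1m to −1.58 ± 0.19, the Y RNA Rny1 to −1.12 ± 0.21, the mitochondrial leucyl-tRNA synthetase Lars2 to −0.98 ± 0.21 and Crlf1 to −0.95 ± 0.19 by the authors' deposited table. Smaller falls in abundant transcripts had small adjusted p-values, as the authors' deposited table showed for Csnk1a1, casein kinase 1 alpha, at −0.52 ± 0.03 (adjusted p = 1.0e-49), and for Chtop at −0.48 ± 0.05 (adjusted p = 5.3e-23).

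Under the same limits on mean and symbol, the zinc finger gene Zfp949 led the rises in whole brain with 1.58 ± 0.08 (adjusted p = 2.2e-91), followed by Mthfs, an enzyme of folate metabolism, with 1.45 ± 0.15 (adjusted p = 3.3e-18), both from the authors' deposited table. Further rises there were 0.93 ± 0.22 for the receptor gene Eda2r, 0.81 ± 0.17 for the glutathione transferase Gsta4, 0.65 ± 0.14 for Zfp951, 0.61 ± 0.11 for Shisa3 and 0.58 ± 0.14 for Zmat1, again by the authors' deposited table. Small rises were called in Tmod2, a neuronal actin-capping protein (0.35 ± 0.04, adjusted p = 4.9e-16), and in the homeobox gene Zfhx4 (0.26 ± 0.04, adjusted p = 4.6e-09) in the authors' deposited table. Xist was lower in whole brain, at −0.44 ± 0.04 or 0.735 of WT (adjusted p = 1.4e-20) in the authors' deposited table; its antisense partner Tsix, chosen after its values were seen, had a mean normalized count of 8.08.

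The calls were not spread evenly over chromosomes. On chromosome 9, which carries Msl2, 58 of 934 tested genes were called in whole brain (6.21%), against 281 of 15760 on the other chromosomes or without a position (1.78%). The X chromosome was next, with 19 of 544 (3.49%). Rpl29, Ooep, Ppm1m, Lars2, Zfp949, Mthfs, Gsta4 and Tmod2 all lie on chromosome 9. Within 25 Mb of the start of Msl2, 42 of 413 tested genes were called in whole brain, and 16 of 521 elsewhere on the chromosome (two-sided Fisher's exact test, p = 8.7e-06). In placenta the counts were 21 of 405 and 11 of 529 (two-sided Fisher's exact test, p = 0.011). The window was chosen after the calls were seen.

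**Figure D1:**
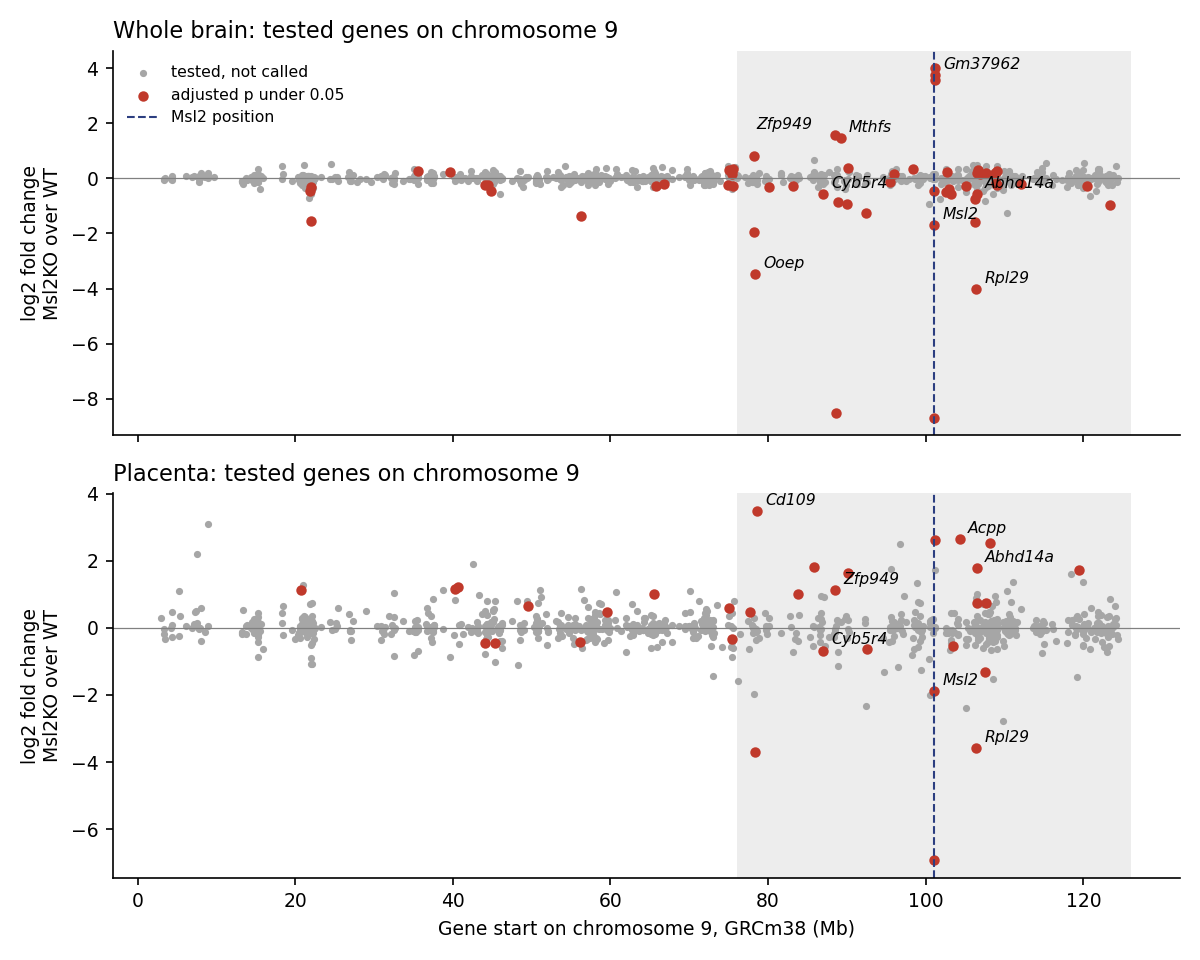
Log2 fold change (Msl2KO over WT) of each tested gene on chromosome 9, as deposited by the authors, against the start of the gene in Mb (build GRCm38), for whole brain (top) and placenta (bottom). Red points have an adjusted p under 0.05, the dashed line marks Msl2 and the shaded band spans 25 Mb on each side of it, where 42 whole brain and 21 placenta calls lie.

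Gene lists described the whole brain change further. Of 46 lists with enough tested members, 8 passed, 1 higher and 7 lower. The Hox genes, which pattern the hindbrain and spinal cord, were higher as a list, with all 15 tested members positive and a median of 0.60 (adjusted p = 4.1e-05). Only Hoxa4 was called over all genes, and 3 were called when adjusted over the list alone. The authors' deposited table gave Hoxa4 0.63 ± 0.17 (adjusted p = 0.015); Hoxb4 at 0.60 ± 0.21, Hoxb2 at 0.47 ± 0.18 and Hoxd3 at 0.40 ± 0.21 were not called. Hox genes overlap each other and antisense transcripts, and the strand setting of the counting is not given. A list of midbrain and hindbrain transcription factors, written after the calls were seen and holding Hox members too, had a median of 0.26, and one of forebrain transcription factors a median of −0.14; both include called genes, so they are no independent evidence.

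GABAergic neuron markers were lower as a list (16 tested, median −0.13, adjusted p = 0.0028), with 3 called lower and 5 adjusted over the list alone. These were the forebrain homeobox genes Arx, at −0.38 ± 0.09, and Dlx1, at −0.30 ± 0.08, and the zinc finger gene Sp8, at −0.42 ± 0.12, in the authors' deposited table; Dlx2 stood at −0.31 ± 0.10 (adjusted p = 0.080). Markers of brain regions moved beside it: 27 of 30 forebrain factors were negative and 45 of 46 midbrain and hindbrain factors positive in the lists written after the calls were seen. Excitatory cortical neuron markers, in a list fixed earlier, were negative in 12 of 16 (adjusted p = 0.071). Astrocyte markers were lower (12 tested, median −0.09, adjusted p = 0.014), 1 of them called, Clu at −0.29 ± 0.06 in the authors' deposited table, and 3 adjusted over the list alone. Raising the preset correlation to 0.05 left the GABAergic list past the threshold and ended the call of the astrocyte list (adjusted p = 0.086).

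Replication-dependent histones were lower (26 tested, 23 negative, median −0.11, adjusted p = 1.8e-06), with 3 called lower and 7 adjusted over the list alone. The linker histones Hist1h1d and Hist1h1c fell by 0.32 ± 0.06 and 0.25 ± 0.06 on the log2 scale, and Hist1h4d fell by 0.23 ± 0.05, in the authors' deposited table. These mRNAs lack a poly(A) tail, and other RNAs without a long tail, examined after the calls were seen, moved beside them. Of 157 small RNAs (snRNA, snoRNA, scaRNA, miRNA and misc_RNA in the annotation), 102 were negative (median −0.080), with 0 called higher and 5 lower, among them Rny1. Both mitochondrial ribosomal RNAs were called lower, mt-Rnr2 at −0.64 ± 0.11 and mt-Rnr1 at −0.40 ± 0.05 in the authors' deposited table. Of 28 S phase genes, 1 was called lower and 2 adjusted over the list alone (median −0.06, adjusted p = 0.036); this was the replicative helicase subunit Mcm5, at −0.65 ± 0.10 in the authors' deposited table. Hypoxia and glycolysis genes were lower (30 tested, median −0.09, adjusted p = 0.0076), with 1 called, Pdk1 at −0.21 ± 0.06 in the authors' deposited table, and 5 adjusted over the list alone. Adjusting over all genes with a p-value ended the call of Pdk1 (adjusted p = 0.067). Clustered protocadherins, adhesion proteins of neurons, were lower as a list (54 tested, median −0.06, adjusted p = 0.027). Over all genes Pcdhgb1 was called higher and Pcdhb11 lower, the latter at −0.45 ± 0.13 in the authors' deposited table, and 1 was higher and 7 lower adjusted over the list alone. The X inactivation list passed (13 tested, median −0.02, adjusted p = 0.036) with Xist as its 1 call, also the 1 call adjusted over the list alone. With a preset correlation of 0.05 the S phase (adjusted p = 0.21), hypoxia (0.12), protocadherin (0.21) and X inactivation (0.17) lists no longer passed, and the X inactivation list did not pass the rank-based form either (adjusted p = 0.35).

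The lists of dosage-sensitive and imprinted genes did not pass in whole brain. Genes whose loss of 1 copy is linked to neurodevelopmental disorders had 61 tested members, 2 called higher and 4 lower (median 0.0036, adjusted p = 0.80), and 2 higher and 5 lower adjusted over the list alone. The higher ones were Ebf3 and Foxp2, and the lower ones were Nfia, at −0.29 ± 0.04, Nfix, at −0.17 ± 0.04, Zeb2, at −0.20 ± 0.05, and the potassium channel gene Kcnq2, at −0.15 ± 0.03, in the authors' deposited table. Paternally expressed imprinted genes had Nnat and Peg13 called higher among 33 (adjusted p = 0.095), with 4 higher and 2 lower adjusted over the list alone. Maternally expressed imprinted genes had H13 called higher among 28 (adjusted p = 0.16), and 3 higher adjusted over the list alone. Without chromosome 9, a choice made after seeing the data, the paternally expressed list passed (adjusted p = 0.026).

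In placenta, of 16616 tested genes 243 were called, 175 higher and 68 lower, with a median absolute log2 fold change of 0.96, and 113 had an absolute value of at least 1, of which 107 were higher. Rescaling the Wald score to its central spread gave 396 in placenta, with 248 higher, and 285 in whole brain, so the order of the tissues by number of calls depends on that setting. Among called genes with a mean of at least 50 and a conventional symbol, the highest were Sfrp5, a secreted Wnt antagonist (4.63 ± 1.22), Prl8a2, the decidual prolactin-related hormone (4.29 ± 1.07), the protease inhibitor Tfpi2 (4.19 ± 1.09), the tight junction gene Cldn11 (4.12 ± 0.89) and the retroviral Erv3 (4.06 ± 0.76) in the authors' deposited table. Sez6l (3.99 ± 0.89), the microfibril gene Mfap5 (3.94 ± 0.86) and Cd109 (3.49 ± 0.81) followed in the authors' deposited table, and all of these had wide standard errors. The smallest adjusted p-values among rises belonged to Acpp (2.64 ± 0.25, 2.0e-21), Prl7b1 (2.00 ± 0.21, 9.1e-19), the retinoic acid enzyme Aldh1a3 (1.54 ± 0.19, 1.3e-12) and Dtna (2.61 ± 0.34, 5.2e-11) in the authors' deposited table.

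Under the same limits, falls in placenta were led by Rpl29, at −3.58 ± 0.18 (adjusted p = 3.2e-81), with Msl2 next, in the authors' deposited table. The serotonin transporter Slc6a4 stood at −0.99 ± 0.26, the matrix enzyme Loxl4 at −0.97 ± 0.26, Tdrd1 at −0.88 ± 0.26, the gluconeogenic Pck2 at −0.87 ± 0.23, the calcium channel Cacna1g at −0.84 ± 0.20 and Bst1 at −0.79 ± 0.23 by the authors' deposited table. Igfbp3, at −0.69 ± 0.13, and Scel, at −0.57 ± 0.10, had an adjusted p of 1.3e-05 each in the authors' deposited table. Tdrd1 (adjusted p = 0.083) and Bst1 (0.067) did not pass when the adjustment ran over all genes with a p-value.

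Genes of the maternal decidua were higher in Msl2KO placenta. The list of decidua and uterine stroma had 14 tested members, 13 of them positive, with a median of 1.00 (adjusted p = 4.1e-14); 5 were called higher and 9 adjusted over the list alone. These included desmin, Des, at 1.89 ± 0.33, the oestrogen receptor Esr1 at 1.56 ± 0.36, Hoxa10 at 1.15 ± 0.31 and Dcn at 1.94 ± 0.54 in the authors' deposited table. Markers of uterine natural killer and cytotoxic lymphocytes were higher too (7 tested, all positive, median 1.71, adjusted p = 6.4e-12). Of these the granzymes Gzmf, at 1.90 ± 0.38, and Gzmd, at 1.82 ± 0.41, were called in the authors' deposited table, and 6 were called adjusted over the list alone. The MHC class I list rose with them (10 tested, median 0.49, adjusted p = 3.3e-15), through H2-D1 at 0.73 ± 0.11, H2-K1 at 0.66 ± 0.10 and B2m at 0.64 ± 0.11 in the authors' deposited table, and 5 were called adjusted over the list alone. Fibroblast markers (14 tested, Dcn and Nov called higher, median 0.04, adjusted p = 0.78) and those of pericytes and smooth muscle (11 tested, Des called higher, median −0.33, adjusted p = 0.56) did not pass. Adjusted over the list alone, 2 fibroblast members were higher and 2 lower, and 3 smooth muscle members were higher and 5 lower. Without the members of the decidual, natural killer, prolactin, fibroblast, smooth muscle and matrix lists, a choice made after seeing the data, 227 of the 243 placenta calls remained. These lists are short and other genes of the same cells stay in, so this count cannot show how many calls come from tissue composition.

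The prolactin family, hormones of trophoblast and decidua, was higher as a list (23 tested, 18 positive, median 0.18, adjusted p = 1.3e-15), alongside the decidual markers. Over all genes 7 members were called higher, and adjusted over the list alone 10 were higher and 2 lower. Beside Prl8a2 and Prl7b1, the authors' deposited table held Prl7c1 at 2.19 ± 0.30, Prl4a1 at 1.27 ± 0.21 and Prl2a1 at 0.77 ± 0.11; Prl2c1 and Prl7a1 were the other 2. The trophoblast giant cell list (13 tested, median 0.18, adjusted p = 3.7e-04) had Prl4a1 and Prl7a1 called, the glycogen trophoblast list (13 tested, median 0.09, adjusted p = 2.6e-05) had Prl7b1 and Aldh1a3, and the spongiotrophoblast list (20 tested, median 0.02, adjusted p = 0.025) had Prl7b1 alone. Adjusted over the list alone, 4, 2 and 2 members were higher, and 1 spongiotrophoblast member was lower. None of these 3 passed the rank-based form, with adjusted p-values of 0.12, 0.13 and 0.34, and the spongiotrophoblast list also failed with a preset correlation of 0.05 (adjusted p = 0.11). Tpbpa, the abundant spongiotrophoblast marker, was not called, at 0.31 ± 0.11 (adjusted p = 0.17) in the authors' deposited table.

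Nutrient transporters were lower in Msl2KO placenta (26 tested, 22 negative, median −0.20, adjusted p = 1.4e-13), with 4 called lower and 12 adjusted over the list alone. In the same libraries decidual (median 1.00) and natural killer (median 1.71) markers were higher, beside this list and the Notch, matrix and histone lists that were lower. The called transporters were the iron exporter Slc40a1, at −0.49 ± 0.09, the glucose transporter Slc2a3, at −0.54 ± 0.13, and the amino acid transporters Slc7a2, at −0.55 ± 0.13, and Slc7a5, at −0.38 ± 0.10, in the authors' deposited table. Notch pathway genes were lower (13 tested, 12 negative, median −0.24, adjusted p = 2.6e-05), with the ligand Dll1 called, at −0.66 ± 0.15 in the authors' deposited table, which was also the 1 call adjusted over the list alone. Extracellular matrix and collagen genes were lower (33 tested, median −0.08, adjusted p = 0.0079); elastin, Eln, at −0.67 ± 0.12, and Nid2, at −0.40 ± 0.11, were called in the authors' deposited table, and 4 adjusted over the list alone. The matrix list passed neither with a preset correlation of 0.05 (adjusted p = 0.10) nor in the rank-based form (0.12). Replication-dependent histones were lower (26 tested, median −0.23, adjusted p = 0.039) with 0 called by the authors' adjusted p and 0 adjusted over the list alone, and did not pass with a correlation of 0.05 (adjusted p = 0.18). Beside them, 122 of 212 small RNAs were negative (median −0.077) with 0 called, and the 2 mitochondrial ribosomal RNAs had a median of 0.63, also with 0 called.

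Other lists were higher in placenta by small amounts. Ribosomal proteins had 66 of 76 members positive (median 0.10, adjusted p = 7.8e-05), with Rps4x called higher at 0.32 ± 0.08 in the authors' deposited table and Rpl29 lower, the same 2 as adjusted over the list alone. This was not particular to placenta, since 60 of 76 were positive in whole brain too (median 0.04). There the list did not pass cameraPR (adjusted p = 0.14), but it passed in the rank-based form and without chromosome 9. Erythroid markers (13 tested, median 0.30, adjusted p = 1.5e-04) had the beta-globin Hbb-bs called at 0.59 ± 0.13 in the authors' deposited table, also the 1 call adjusted over the list alone. Interferon-stimulated genes (35 tested, 30 positive, median 0.18, adjusted p = 8.2e-04), heat shock genes (13 tested, all positive, median 0.14, adjusted p = 0.0016) and mitochondrially encoded transcripts (9 tested, median 0.19, adjusted p = 0.040) passed with 0 members called by the authors' adjusted p and 0 adjusted over the list alone. The mitochondrial list did not pass with a correlation of 0.05 (adjusted p = 0.10) or among genes with a mean normalized count of at least 50 (adjusted p = 0.057). Endothelial markers (15 tested, median −0.08, adjusted p = 0.13) and those of syncytiotrophoblast and labyrinth (18 tested, median −0.14, adjusted p = 0.29) did not pass. The first had 0 called and the second 1 higher, Lgals9, and adjusted over the list alone these were 0, and 2 higher and 1 lower. Maternally expressed imprinted genes had 2 called higher (Dcn and Tfpi2) and 2 lower (Cobl and Grb10) among 31 (adjusted p = 0.13), with 3 and 3 adjusted over the list alone, and Grb10, a growth restraining adaptor, stood at −0.33 ± 0.08 in the authors' deposited table. Paternally expressed ones had Mest called lower among 33, at −0.39 ± 0.08 in the authors' deposited table (list adjusted p = 0.074), and 2 lower adjusted over the list alone. By choices made after seeing the data, the paternal list passed as lower without chromosome 9 (adjusted p = 0.036), and the maternal list passed as lower among genes with a standard error of at most 0.5 (adjusted p = 0.0031). That limit leaves out Dcn and Tfpi2 (standard errors 0.54 and 1.09), the 2 members called higher. The result for the maternal list therefore cannot decide its direction.

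**Figure D2:**
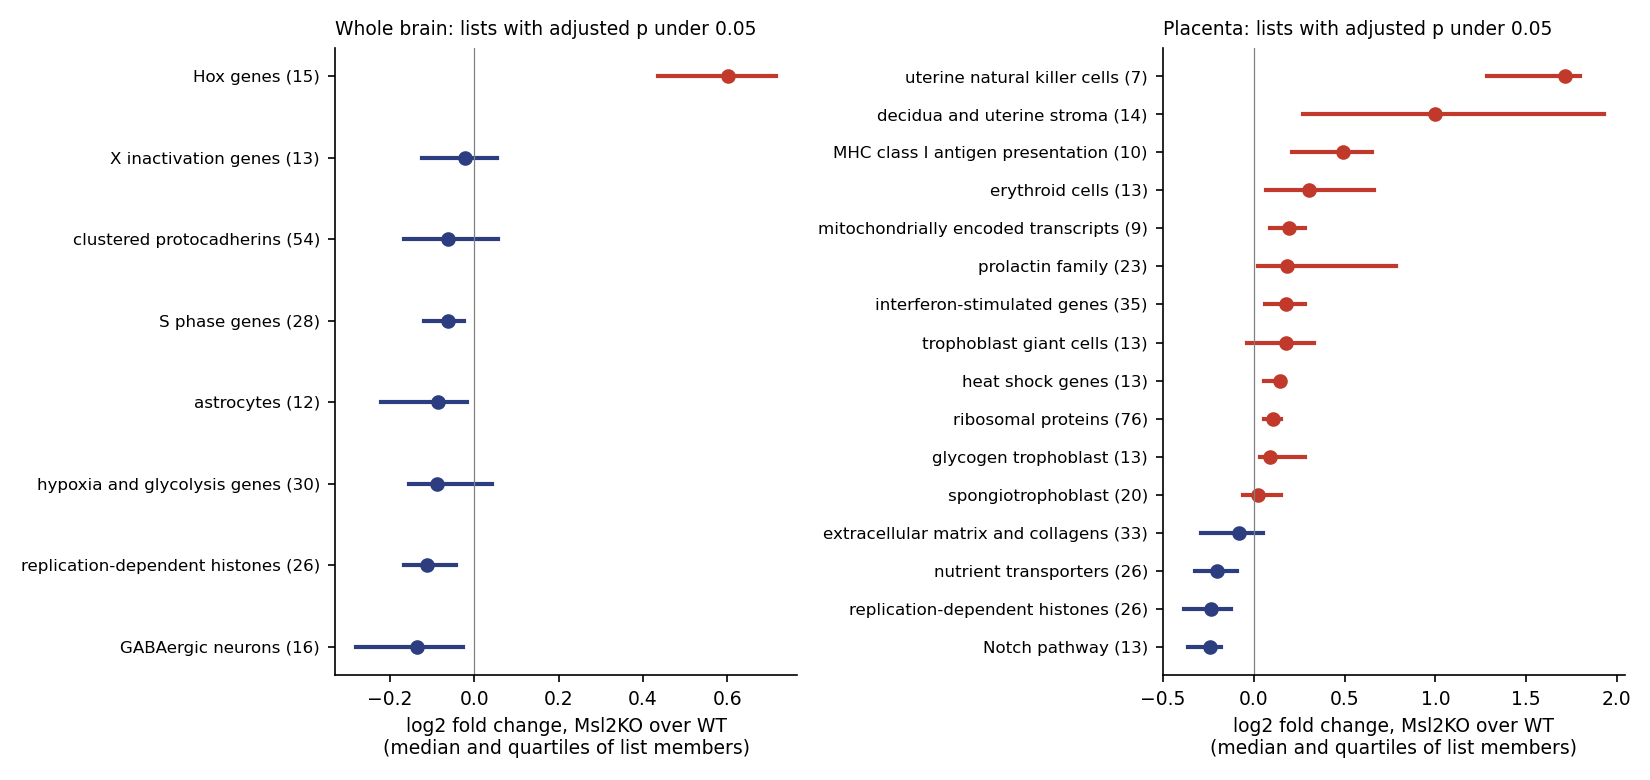
Median (point) and quartiles (line) of the authors' log2 fold changes over the tested members of each list that passed, with the number of members in brackets, for whole brain (left) and placenta (right); red lists were higher and blue lists lower by cameraPR. Hox genes had the highest median in whole brain (0.60), and natural killer (1.71) and decidual (1.00) markers in placenta.

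**Figure D3:**
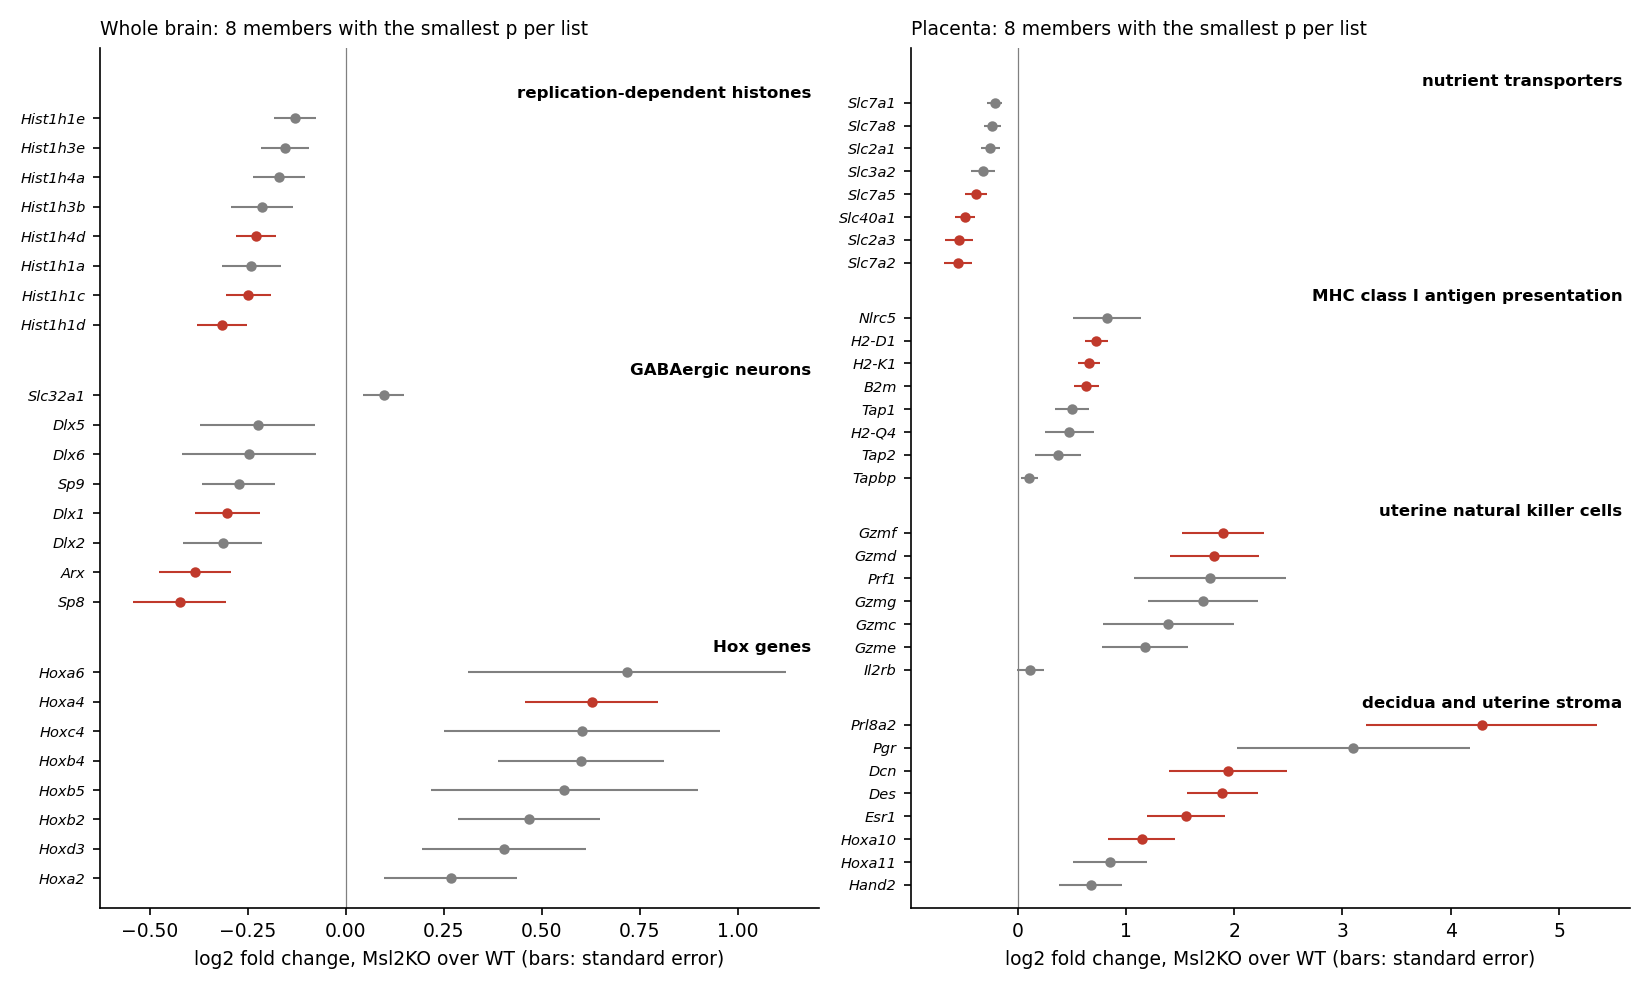
Log2 fold change with its standard error (bar), as deposited by the authors, for up to 8 members with the smallest p-value in lists of whole brain (left) and placenta (right); red members have an adjusted p under 0.05 and grey ones do not. The called granzymes lie at 1.82 and 1.90, and the called transporters between −0.55 and −0.38.

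Over all tested genes, calls were shared between the tissues more often than independent lists would give, but less clearly so without chromosome 9. Among 14184 genes tested in both, 9 were called higher in both, against 1.05 for independent lists (one-sided Fisher's exact test, p = 1.0e-06), and 5 lower in both, against 0.694 (one-sided Fisher's exact test, p = 6.3e-04). The lower ones include Msl2, which the knockout itself removes, and Gm37553, a locus in its intron. Without these 2, a choice made after seeing the data, 3 were lower in both (Rpl29, Cyb5r4 and Eln; one-sided Fisher's exact test, p = 0.028). With a mean of at least 50 in both tables, 3 were higher in both (one-sided Fisher's exact test, p = 0.039) and 4 lower (one-sided Fisher's exact test, p = 0.0047). Of the 16 genes called in both tissues, 14 had the same direction. Rpl29 and Msl2 fell in both, with Cyb5r4, a cytochrome b5 reductase, at −0.59 ± 0.07 in whole brain and −0.68 ± 0.13 in placenta in the authors' deposited tables. Zfp949 rose in both, to 1.14 ± 0.21 in placenta, as did Shisa3, to 4.61 ± 0.52 there, in the authors' deposited table. The authors' deposited tables also gave rises for Gm8210, a pseudogene with 99.4% identity to Rpl29 (9.26 ± 1.20 in whole brain and 7.45 ± 1.37 in placenta), and Gm11868, a pseudogene with 98.0% identity to Cyb5r4 (3.65 ± 0.26 and 3.67 ± 0.42). Reads may be divided between these pairs. Leaving out chromosome 9, an alternative chosen after seeing the data, left 6 genes called in both. Independent lists would give 2.79 (one-sided Fisher's exact test, p = 0.061). Of the 6, 5 were higher (one-sided Fisher's exact test, p = 0.0013) and 1 lower (one-sided Fisher's exact test, p = 0.38). Of those 5, the pseudogenes Gm8210, Gm13841 and Gm11868 match Rpl29 or Cyb5r4, which lie on chromosome 9 near Msl2, so this setting does not remove what those genes bring. The other 2 were Shisa3 and, chosen after its values were seen, Kif21b.

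The log2 fold changes differed between tissues for 114 genes, with placenta above whole brain in 88 and below in 26. With the score of the difference rescaled, 141 lay above and 65 below, and at an adjusted p under 0.01, 52 and 9. Des, of the decidual list, is among the 88. A larger share of decidua in the Msl2KO placenta libraries could raise such values, but this was not tested for the genes that differed between tissues. Abhd14a, an alpha/beta hydrolase gene that starts at 106440051 on chromosome 9, beside Rpl29, was lower in whole brain (−0.57 ± 0.09) and higher in placenta (1.77 ± 0.33) in the authors' deposited tables, a difference of 2.35 ± 0.34 (adjusted p = 3.3e-08). Dtna differed by 2.68 ± 0.35 (adjusted p = 1.4e-10), Shisa3 by 4.00 ± 0.53 (adjusted p = 2.8e-10) and Gramd1b by 1.25 ± 0.18 (adjusted p = 2.1e-08), each higher in placenta. S100a1 fell in whole brain and stood at −0.24 ± 0.15 in placenta in the authors' deposited table, a difference of 1.81 ± 0.29 (adjusted p = 6.6e-07). For Xist, which was called in whole brain and stood at −0.09 ± 0.10 in placenta in the authors' deposited table, the difference of 0.36 ± 0.11 did not pass (adjusted p = 0.076).

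**Figure D4:**
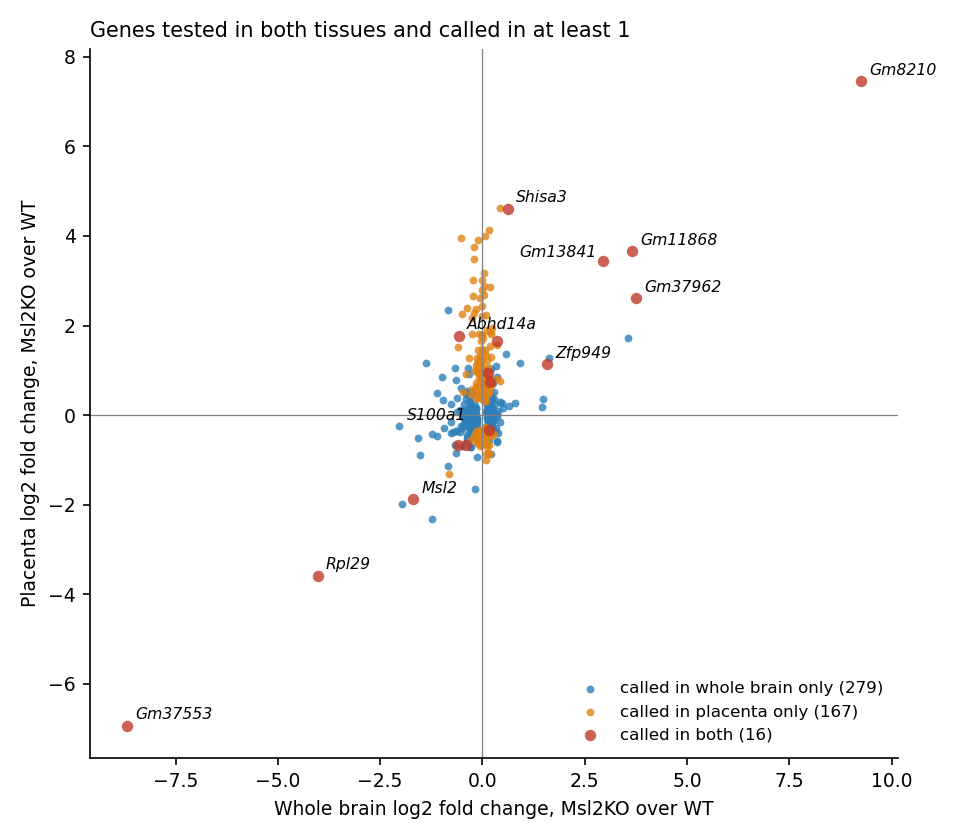
Log2 fold changes (Msl2KO over WT) as deposited by the authors, whole brain on the horizontal and placenta on the vertical axis, of genes tested in both tissues and called in at least 1; colours separate genes called in whole brain, in placenta or in both. Of the 16 red genes called in both, Rpl29 lies at −4.03 and −3.58 and Gm8210 at 9.26 and 7.45, while Abhd14a lies in opposite directions.

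Because the MSL complex equalises X-linked expression in male flies, X-linked genes were compared with autosomal ones. In whole brain the median log2 fold change of 624 X-linked genes lay 0.0036 below that of 18139 autosomal genes, at percentile 23.6 of 10000 expression-matched lists. In placenta the median of 523 X-linked genes lay 0.017 below that of 14501, at percentile 3.36. A shift of X-linked genes did not pass cameraPR in whole brain (adjusted p = 0.50, a single test) or placenta (adjusted p = 0.26). The preset correlation widens that test for lists this long, so a small shift is not excluded. With means in place of medians the placenta difference was −0.052, at percentile 0.04, and with a mean normalized count of at least 100 its median difference was −0.0018, at percentile 42.7. X-linked genes were called more often than autosomal genes off chromosome 9 in whole brain, 19 of 544 (3.49%) against 259 of 15124 (1.71%; two-sided Fisher's exact test, p = 0.0045, chosen after seeing the data), 7 of them higher and 12 lower. In placenta the counts were 6 of 568 and 205 of 15032 (two-sided Fisher's exact test, p = 0.71).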

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

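The tests of expression level, near neighbours and linked variants on chromosome 9, of decidual share, of labyrinth share as the whole of the decidual rise and of uneven dissection were chosen after the results were seen. By the difference test, the log2 fold changes of placenta and whole brain differed in 114 genes. Values are placenta minus whole brain with the standard error of the difference, for genes picked by rank under the naming rule whose difference passed at an adjusted p under 0.05. Other genes named in the text passed too, namely Ppp2r3a (0.45 ± 0.10), Nov (1.90 ± 0.48), Mest (−0.49 ± 0.10) and Cobl (−0.62 ± 0.16). Placenta lay above whole brain for Dtna by 2.68 ± 0.35, Shisa3 by 4.00 ± 0.53, Gramd1b by 1.25 ± 0.18, Abhd14a by 2.35 ± 0.34, S100a1 by 1.81 ± 0.29, Noct by 0.76 ± 0.12, Emilin2 by 2.52 ± 0.41 and Crabp2, a retinoic acid binding protein, by 3.96 ± 0.66. It also lay above for H2-D1 by 0.74 ± 0.13, B2m by 0.78 ± 0.15, Mfap5 by 4.47 ± 0.95, Cd109 by 3.70 ± 0.83, Cldn11 by 3.96 ± 0.90, Sez6l by 3.93 ± 0.89, Ppm1m by 1.05 ± 0.27, Crlf1 by 1.29 ± 0.35, Aldh1a3 by 1.35 ± 0.37 and Des by 1.77 ± 0.49. Placenta lay below whole brain for Dll1 (−0.82 ± 0.17), Cacna1g (−0.98 ± 0.21), Slc7a5 (−0.48 ± 0.11), Igfbp3 (−0.63 ± 0.15), Slc40a1 (−0.49 ± 0.13), Slc6a4 (−1.08 ± 0.28), Pck2 (−0.95 ± 0.26) and Slc2a3 (−0.51 ± 0.14).

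Called genes gathered on chromosome 9 around Msl2, with 42 calls within 25 Mb in whole brain and 21 in placenta. Among 10000 expression-matched lists of genes on other chromosomes or without a position, the most were 20 and 15. Those matched genes were thus called less often, but the window was chosen after the calls were seen, and its counts include Msl2 and Gm37553. The comparison therefore cannot exclude expression level as a source. Near neighbours of the locus do not account for most of the gathering, since 5 of 57 whole brain calls on the chromosome (8.77%), Msl2 left out, lay within 1 Mb. The odds of a call were higher within 25 Mb than elsewhere on chromosome 9, by an odds ratio of 3.57 in whole brain (95% interval 1.93 to 6.91) and 2.57 in placenta (1.17 to 5.98). That window was chosen after the calls were seen, so the ratios restate the pattern, and sequence or regulatory differences of another strain, carried along with the knockout allele, cannot be told apart from a wider effect of Msl2 loss on the region, since no genotypes were used here.

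Decidual genes were higher in Msl2KO placenta, with a list median of 1.00, together with natural killer markers. A lower share of labyrinth would raise spongiotrophoblast and decidual markers alike. Yet the mean log2 fold change of the decidual list lay 1.18 ± 0.38 above that of the spongiotrophoblast list. Errors of list means in this paragraph rest on the spread between list members, not between libraries, and the bound was written after the results were seen. A lower share of labyrinth as the whole of the rise is therefore not decided by this gap. Whether it contributes cannot be told apart. The bound set earlier on endothelial markers (mean Wald score −0.61) was wrong because the labyrinth holds the fetal vessels. Labyrinth markers stood at −0.42 ± 0.47, and nutrient transporters were lower. Erythroid markers were higher (mean Wald score 1.34 ± 0.47), but whether that blood was fetal or maternal was not tested, so they decide nothing here. A larger share of maternal decidua in the 2 Msl2KO libraries may account for the decidual rise, as could a change of the decidua itself, which was not tested apart from it. Uneven dissection within a group cannot be told apart from these: against expression-matched genes the standard errors of decidual genes were 1.29 times as large at the median, and the ratio was 7.93 for Prl8a2, 5.21 for Dcn, 3.22 for Pgr, 2.93 for Cryab, 2.52 for Des and 2.48 for Dio2 but 1.01 for Esr1 and 1.16 for Hoxa10, both called.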

How the results depend on the processing

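No paired analysis was possible because the tables used hold no values per sample. For the same reason a replicate block, leaving out each replicate, edgeR normalization, a run without a filter, a pseudocount, an estimated correlation for cameraPR and other splits of the samples were not run, and effects of depth could not be examined. Of the results followed, 0 turned in direction under any setting run. For single genes this says little, because every setting but centring kept the authors' fold change. Centring subtracted only 0.0046 in whole brain and −0.010 in placenta. A threshold of 0.01 gave 204 genes in whole brain, 151 in placenta and 61 differing between tissues, and an absolute log2 fold change of at least 1 gave 25 and 113; these follow from stricter thresholds. Rescaling the test score gave 396 placenta genes, which contain all 243, and 206 tissue differences, which contain all 114, because the central spread of the score was below 1 (0.862 and 0.875). In whole brain that spread was 1.04 and the count 285. Genes called in both tissues numbered 9 with a mean of at least 50 in both tables, and 6 without chromosome 9, an alternative chosen after seeing the data; both settings test fewer genes. In whole brain 3 lists passed with a preset correlation of 0.05, which widens the test. Without chromosome 9, also chosen after seeing the data, 16 passed, including the 8. That setting leaves out Rpl29 (−4.03 ± 0.21), a member of the ribosomal protein list, in which 60 of 76 members were positive. The cause of the rise in the number of lists was not tested. The 8 gained were Notch, cholesterol, microglia, fibroblast, radial glia, excitatory cortical, paternally imprinted and ribosomal protein genes (the last at adjusted p = 6.6e-04). The rank-based form also added 5 whole brain lists: ribosomal protein (adjusted p = 1.4e-04), Notch (0.025), cholesterol (0.026), microglia (0.035) and MHC class I genes (0.035). In placenta it added G2 and M phase genes (adjusted p = 0.039). The other counts stayed within 1.5 times, from 276 to 420 genes in whole brain and 209 to 285 in placenta.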

Other observations

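The tests of the regional lists in whole brain and of the parents of pseudogenes were chosen after the results were seen, as were the loci beside Msl2. Among transcription factors of midbrain and hindbrain, 11 were called higher in Msl2KO whole brain and 45 of 46 were positive (median 0.26), with 15 called adjusted over the list alone. These were Barhl1, En1, Gata3, Hoxa4, Lhx1, Mab21l2, Pou4f2, Tfap2a, Tfap2d, Pou4f1, a factor of sensory and midbrain neurons, at 0.37 ± 0.08, and Tal1 at 0.38 ± 0.08 in the authors' deposited table. Among forebrain factors, 4 of 30 were called lower and 3 were positive (median −0.135), with 5 called adjusted over the list alone. Beside Arx and Dlx1, also in the GABAergic list, these were Fezf2 at −0.36 ± 0.11 and Neurod2 at −0.21 ± 0.06 in the authors' deposited table. Adjusting over all genes with a p-value ended the calls of Fezf2 (adjusted p = 0.075) and Neurod2 (0.057).

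Both regional lists were written once the calls were seen and hold called genes, and that of midbrain and hindbrain holds Hox members. A test on them therefore decides nothing, and the counts adjusted over each list alone decide nothing either. No list test is given for the forebrain median of −0.135 or its counterpart. Of the lists fixed earlier, excitatory cortical neurons (12 of 16 negative, adjusted p = 0.071) and cerebellar and hindbrain neurons (7 of 13 positive, adjusted p = 0.14) did not pass. Without chromosome 9, a choice made after seeing the data, the cortical list passed as lower (adjusted p = 0.039) and the hindbrain list did not (0.19). A larger share of midbrain and hindbrain in the Msl2KO libraries cannot be told apart from a change in regional identity or cell number, since values per sample were not used.

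Loci beside Msl2 on chromosome 9 were chosen after their values were seen. Ppp2r3a, a phosphatase subunit gene on the minus strand from 101105084 to 101251795, has its 3' end 0.284 kb past the end of Msl2 and stood at −0.46 ± 0.05 in whole brain (adjusted p = 1.8e-16) and −0.01 ± 0.08 in placenta in the authors' deposited tables. On the plus strand within its span, the unclassified loci Gm37962, Gm37621 and Gm37953 were higher in whole brain, at 3.75 ± 0.16, 3.57 ± 0.13 and 3.99 ± 0.31 in the authors' deposited table, and lie 9.01, 11.9 and 45.5 kb past the end of Msl2. In placenta the authors' deposited table held 2.61 ± 0.64 for Gm37962 (called) and 1.73 ± 0.63 for Gm37621 (adjusted p = 0.23), and Gm37953 was not tested. Gm37553, a plus strand locus inside an intron of Msl2, stood at −8.69 ± 1.21 in whole brain and −6.93 ± 1.54 in placenta in the authors' deposited tables.

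A hypothesis is that sequence differences near Msl2 send reads of a parent gene to a pseudogene elsewhere. Of 5 pseudogenes called higher in whole brain with a close protein-coding match, 4 (80%) had the parent within 25 Mb of Msl2, but 3 of them (Gm8210, Gm13841 and Gm11868) prompted the idea, and 2 of those share the parent Rpl29. The 3 are also the ones called higher in placenta, so placenta adds no separate test. Of the other 2 in whole brain, 1 had its parent near Msl2, too few to decide. Of the 3 pseudogenes called higher in both tissues, 2 had Rpl29 as best match and 1 had Cyb5r4, and those 2 gained 5.23% of the normalized counts that Rpl29 lost in whole brain. With 3 looser matches of positive fold change, none of them called, the gain was 5.91%. Whether moved reads are the whole of the fall of Rpl29 cannot be told apart from lower expression, because the treatment of reads with several matches is not given in the sources used here.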
